A study of Mus musculus with 3 samples.

How the data were processed

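Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on mouse embryonic fibroblasts of the C57BL/6 strain, primary cells taken at embryonic day 13.5. Per the labels' protocols, the cells were plated for 24 hours and then kept for 3 hours in amino acid deprived (AAD) medium before formaldehyde fixation. There were 3 libraries, 1 each for an ATF4 antibody, a CEBPG antiserum and a GFP antibody. Each library was sequenced on its own lane with single-end reads of 36 bp, per the labels' protocols. The ATF4 and CEBPG peak lists were used here, and the GFP library was not analysed here.

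The submitters' processing notes name Trimmomatic, BWA, MACS 1.4.2, HOMER and the build mm10, with no settings. Per the deposited files, each list came from its own library, and no pooling of samples is recorded. Whether the GFP library served as background for peak calling is not given in the sources used here. Each deposited file holds the position of each peak and a name that ends in the peak's own score. Column 5, where a BED file normally carries a score, was blank, and column 6 held 0 throughout. The score was therefore read from the end of the peak name in column 4. The deposited scores begin at 40 and look like the scale of MACS, a multiple of the negative log10 of a p-value, although no header states this. They are the authors' values and were used to rank, describe and filter peaks within a list. No read counts or coverage were in these files, so the depth of the libraries is unknown, and the number of peaks in a list cannot be corrected for it.

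Positions are given 1-based in mm10. Gene positions came from a RefSeq gene table of GRCm38.p6, the same build, restricted to 21883 protein-coding genes on the nuclear chromosomes. That table gives each gene's span without its strand, exons or transcripts. The start of a gene could not be told from its end, so the planned distance to a start was replaced by the distance to either end of the gene span, for listed and random genes alike. The planned motif tests, with 11 sequence motifs, were not run because no genome sequence was used here.

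A shared peak was one that overlapped a peak of the other list by at least 1 bp. Overlap was compared with 1000 random placements of the ATF4 peaks on their own chromosomes, between the first and last peak of either list, and the p-value is one-sided. The alternatives with centres within 250 bp and with 50% of both peaks overlapping used 100 placements. Unmappable stretches could not be excluded from these placements. Scores and widths of shared and other peaks were compared with a two-sided permutation test of the difference of medians (100000 resamples). Shares of peaks within 1 kb of a gene end were compared with Fisher's exact test, two-sided, and with 100 random placements. Intervals of shares are 95% Wilson intervals and cover counting error only.

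The 14 gene lists (246 genes, all matched, 1 through a synonym) were assembled from general knowledge before the data were examined. They cover amino acid synthesis and one-carbon metabolism, amino acid transporters, aminoacyl-tRNA synthetases, stress-response regulators, autophagy, glutathione and antioxidant genes, endoplasmic reticulum chaperones, amino acid sensing, inflammatory secreted factors, extracellular matrix, ribosomal proteins, and neuronal, blood-cell and hepatocyte genes. The overlap rule, the tests and the rule for named genes were also fixed before the data were examined. A gene counted as carrying a peak when a peak overlapped the 5 kb on either side of an end. Counts were compared with 10000 random lists of the same size drawn from all protein-coding genes (one-sided), with Benjamini-Hochberg adjustment over the 14 lists of each antibody. Named genes were those nearest the 10 highest-scoring peaks of each list and the 10 shared pairs with the lowest sum of ranks, up to 4 members of each list with the highest scores, and 12 genes named whatever their values. Where the CEBPG list had tied top scores, peaks above the tie were named. A few single-gene values that this rule would name are not reported here. Alternatives changed the overlap rule, the score minimum, the placement, the distance to a gene end and the pool of random genes. In 1 of them, random genes came from those with a CEBPG peak, in the same of 9 classes of their top CEBPG score within 5 kb of an end. List genes stayed in these pools, which makes the test conservative where a class holds few genes.

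With 1 library per antibody, every p-value describes these peak lists and not the spread between cultures. On simulated data with the real peak widths and chromosome spans, 20% of 2642 ATF4 peaks planted on CEBPG peaks were recovered as 20.2%. For gene lists, real genes were marked directly, without placing peaks, and all 10 planted lists were recovered. The planted peaks were centred on CEBPG peaks, and the planted lists had 8 of 16 genes marked. This checks the counting of overlaps and the comparison with random lists at large effects. It does not check the step from peaks to genes, or the power for lists with few peaks. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.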

Results

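The binding of the basic leucine zipper (bZIP) transcription factors ATF4 and CEBPG was mapped by ChIP-seq in mouse embryonic fibroblasts deprived of amino acids for 3 hours. ATF4 is the main transcriptional effector of the amino acid response, and CEBPG is a C/EBP family member that forms heterodimers with ATF4. There was 1 library per antibody and no replicate, so no value below carries an error between cultures. The CEBPG list held 25419 peaks covering 4279 kb, and the ATF4 list held 2642 peaks covering 573 kb. The CEBPG list was thus 9.62 times longer, at library depths that are not known. Peaks were narrow, with a median width of 131 bp for CEBPG and 164 bp for ATF4. Low scores dominated both lists. Scores under 50 made up 60.2% of CEBPG peaks (15307) and 67.9% of ATF4 peaks (1795), and scores of 100 or more made up 11.7% (2982) and 5.11% (135). The median score was 47.2 for CEBPG and 45.9 for ATF4, and the highest scores were 3205.83 and 1152.06. In the CEBPG list 38 peaks shared the score 3100, which looks like a ceiling, and 4 peaks lay above it.

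The first comparison asked how far the sites of both factors coincide. Most of the strong ATF4 sites were also CEBPG sites. The ATF4 peaks at Chac1 (a glutathione-degrading enzyme), Shmt2 (mitochondrial serine hydroxymethyltransferase), Asns (asparagine synthetase) and Psat1 (phosphoserine aminotransferase) each lay on a CEBPG peak. Over the whole list, 400 of 2642 ATF4 peaks (15.1%, 95% Wilson interval 13.8 to 16.6%) overlapped a CEBPG peak. Random placement gave a mean of 0.399%, so the overlap was 37.9 times that of chance, with a one-sided permutation p of 0.001, the smallest that 1000 placements can give. The excess was 23.3-fold against placements 10 to 100 kb from each peak, and 70.4-fold where at least 50% of both peaks had to overlap (100 placements, one-sided permutation p = 0.01, the smallest these can give). In the other direction, 401 of 25419 CEBPG peaks (1.58%, 1.43 to 1.74%) overlapped an ATF4 peak. The centres of the 404 overlapping pairs lay a median of 44 bp apart, and 84.2% of them were within 100 bp of each other.

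The share of shared peaks was higher at higher scores in both lists, apart from the single ATF4 peak above 1000, which was not shared. It was 5.68% for ATF4 peaks with scores from 40 to 50, 39.6% from 60 to 80 and 81.5% (74.1 to 87.1%) for the 135 peaks of 100 or more. Among CEBPG peaks the share was 0.118% from 40 to 50, 23.3% from 500 to 1000 and 62.5% (56.9 to 67.8%) for the 296 peaks of 1000 or more. Of the 42 CEBPG peaks at or above the score 3100, 40 lay on an ATF4 peak. The 2 others lay inside Anks1b and 342 kb from Zeb2. The median score of shared CEBPG peaks was 872.58 (n = 401), against 47.11 for the remaining 25018. Shared ATF4 peaks had a median of 64.68 (n = 400), against 44.94 for the other 2242. Both differences passed a two-sided permutation test (p = 1e-05 each, the smallest that 100000 resamples can give). Across the shared pairs, which are not independent replicates, ATF4 and CEBPG scores had a Spearman rho of 0.55 (permutation p = 0.0001, the smallest possible with 10000 resamples).

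**Figure D1:**
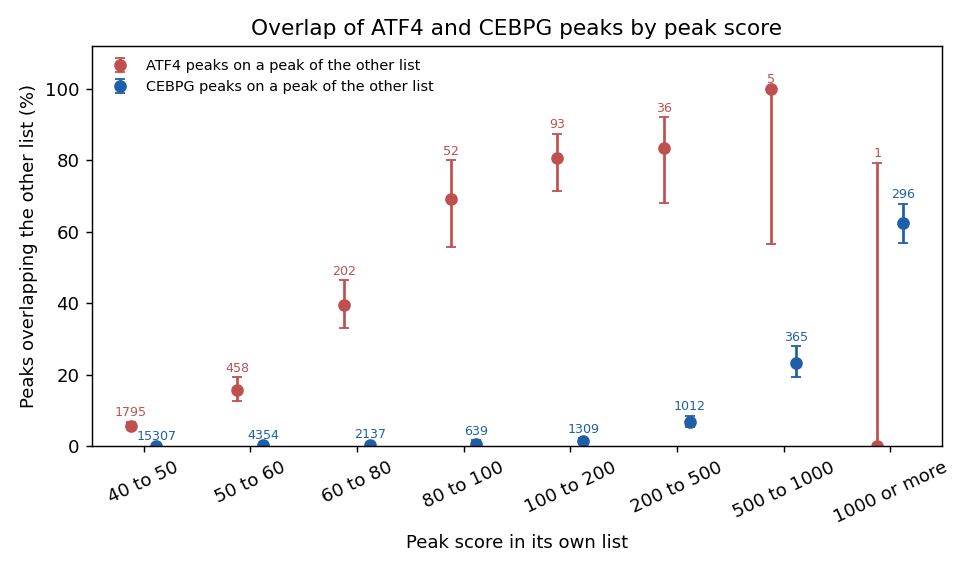
Share of ATF4 peaks (red) and CEBPG peaks (blue) that overlap a peak of the other list by at least 1 bp, in percent, against the peak's score in its own list. Bars are 95% Wilson intervals and the number at each bar is the number of peaks; the ATF4 share climbs from 5.68% to over 80%, except for the single ATF4 peak above 1000, and the CEBPG share reaches 62.5%.

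The strongest shared sites ranged from just outside or within protein-coding genes to far from any of them, and 1 of the first 10, at Chac1, lay next to a gene of the fixed stress list. By the sum of both ranks, the first 10 pairs lay nearest to Klf4, Chac1, Gm42048, Arntl, Lcorl, Ubr2, Taf15, Arl14ep, Auts2 and Slc24a2. The Chac1 pair held the second-highest ATF4 score of the list (841.75, chromosome 2, 119350638 to 119351307) and a CEBPG score of 3100. The ATF4 peak was centred 269 bp outside the Chac1 gene span. The pair nearest Klf4, a zinc-finger transcription factor gene, was 198 kb away (ATF4 score 274.02, CEBPG score 3198.58), and the pair nearest Arntl, a circadian clock gene, was 38.3 kb away (ATF4 score 574). The pairs at Taf15 and Arl14ep had ATF4 peaks centred 697 bp and 183 bp outside those genes. Those at Ubr2, Auts2 and Slc24a2 lay inside the gene, and those nearest Gm42048 (771.89) and Lcorl (551.86) lay 7.32 kb and 17.9 kb from it. Of the other peaks among the 10 highest ATF4 scores, 1 lay inside Shmt2 (526.4). The others lay outside genes, 7.12 kb from Tgif1 (430.44), 7.06 kb from 9230019H11Rik (444.85), 165 kb from Dpt (442.23) and 164 kb from Tcte2 (1152.06). The peaks nearest Tcte2 and 9230019H11Rik were 2589 bp and 3194 bp wide and overlapped no CEBPG peak. The 4 CEBPG peaks above the tied score lay inside Sars, seryl-tRNA synthetase (3205.83), 6.99 kb from Serpinh1, a collagen chaperone (3205.56), near Klf4, and 6.55 kb from Vldlr, a lipoprotein receptor (3133.62). Each of these 4 overlapped an ATF4 peak.

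Shared CEBPG peaks lay near gene ends more often than other CEBPG peaks. Of 401 shared peaks, 47 (11.7%, 8.93 to 15.2%) were centred within 1 kb of an end of a protein-coding gene, against 1053 of 25016 (4.21%, 3.97 to 4.47%) CEBPG peaks without an ATF4 peak (Fisher's exact test, two-sided, p = 6.46e-10). Random placement gave 3.17% and 3.02% for the same sets. The 2242 ATF4 peaks outside the CEBPG list reached 3.61%, within the range of their 100 placements (up to 3.93%). Shared peaks differ from the rest in score as well. Against CEBPG peaks matched by score, a comparison added after seeing the data, the share was 11.7% against 7.23% (401 each, Fisher's exact p = 0.0398). The match was incomplete, with a median score of 744.77 in the matched set. Gene ends were not the main location. Of the 401 shared CEBPG peaks, 206 lay outside genes and more than 1 kb from any end.

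The second group of comparisons asked which genes carried the peaks. The lists of amino acid synthesis, aminoacyl-tRNA synthetases and stress-response regulators passed in both peak lists, and amino acid transporters passed for CEBPG alone at this distance. The stress-response list is mixed, with an enzyme gene (Chac1), a receptor gene (Vldlr) and genes already known to be induced by ATF4, such as Trib3. Its pass is therefore not independent of earlier knowledge of ATF4. The same limit applies to the amino acid synthesis, transporter and synthetase lists. They too were assembled from general knowledge, in which ATF4 is the main effector of the amino acid response. Of the 70 genes in the lists for amino acid synthesis, amino acid transport, aminoacyl-tRNA synthetases and stress-response regulators, 55 had a CEBPG peak within 5 kb of an end and 24 had an ATF4 peak. All 24 genes with an ATF4 peak also had a CEBPG peak, and for 22 of them the peaks overlapped. Among all 21883 protein-coding genes, 3609 (16.5%) had a CEBPG peak, 447 (2.04%) an ATF4 peak and 187 both.

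Among stress-response regulators, 18 of 21 carried a CEBPG peak and 11 an ATF4 peak, where random lists averaged 3.44 and 0.432 (adjusted permutation p = 0.00035 and 0.0007). Chac1 (ATF4 score 841.75), Vldlr (275.2) and Ddit4, an inhibitor of mTORC1 (199.36), had overlapping peaks. The Vldlr pair lay on chromosome 19 at 27216580 to 27216954 for ATF4, inside the gene and 287 bp from an end, with a CEBPG score of 2042.82. At Sesn2, a leucine-sensing stress protein, both factors had a pair of overlapping sites. The stronger was 3715 bp from the gene (ATF4 score 164.36, CEBPG 3100) and the weaker inside it (52.08 and 267.95). Trib3, a pseudokinase induced by ATF4, had overlapping peaks at its higher-coordinate end with a CEBPG score of 1007.02 and an ATF4 score of 46.24. Cebpb had both peaks inside its span without overlap. ATF4 covered chromosome 2 from 167689575 to 167689889 (score 282.46) and CEBPG covered 167690007 to 167690416 (845.58). Atf5, another bZIP gene of the list, had overlapping peaks (145.38 for ATF4, 2765.18 for CEBPG). Some members had CEBPG peaks and no ATF4 peak. Ddit3, encoding CHOP, had CEBPG peaks of 351.41 and 57.15, Atf3 had one of 725.28 and Cebpg one of 402.96, each within 1 kb of a gene end. Atf4 itself had no peak in either list within 5 kb.

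In amino acid synthesis and one-carbon metabolism, 13 of 16 genes carried a CEBPG peak and 8 an ATF4 peak, against random means of 2.64 and 0.331 (adjusted permutation p = 0.00035 and 0.0007). At all 8 the peaks overlapped. Scores were 526.4 for ATF4 and 2510.62 for CEBPG at Shmt2, 259.71 and 2842.47 at Pck2 (mitochondrial phosphoenolpyruvate carboxykinase), 188.31 and 1554.72 at Asns, and 180.22 and 3100 at Psat1. The Asns peaks lay on chromosome 6 at 7692952 to 7693445 for ATF4 and 7692891 to 7693576 for CEBPG, both spanning the higher-coordinate end of the gene (7693209). The Psat1 ATF4 peak was centred 104 bp beyond the gene's end on chromosome 19.

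**Figure D2:**
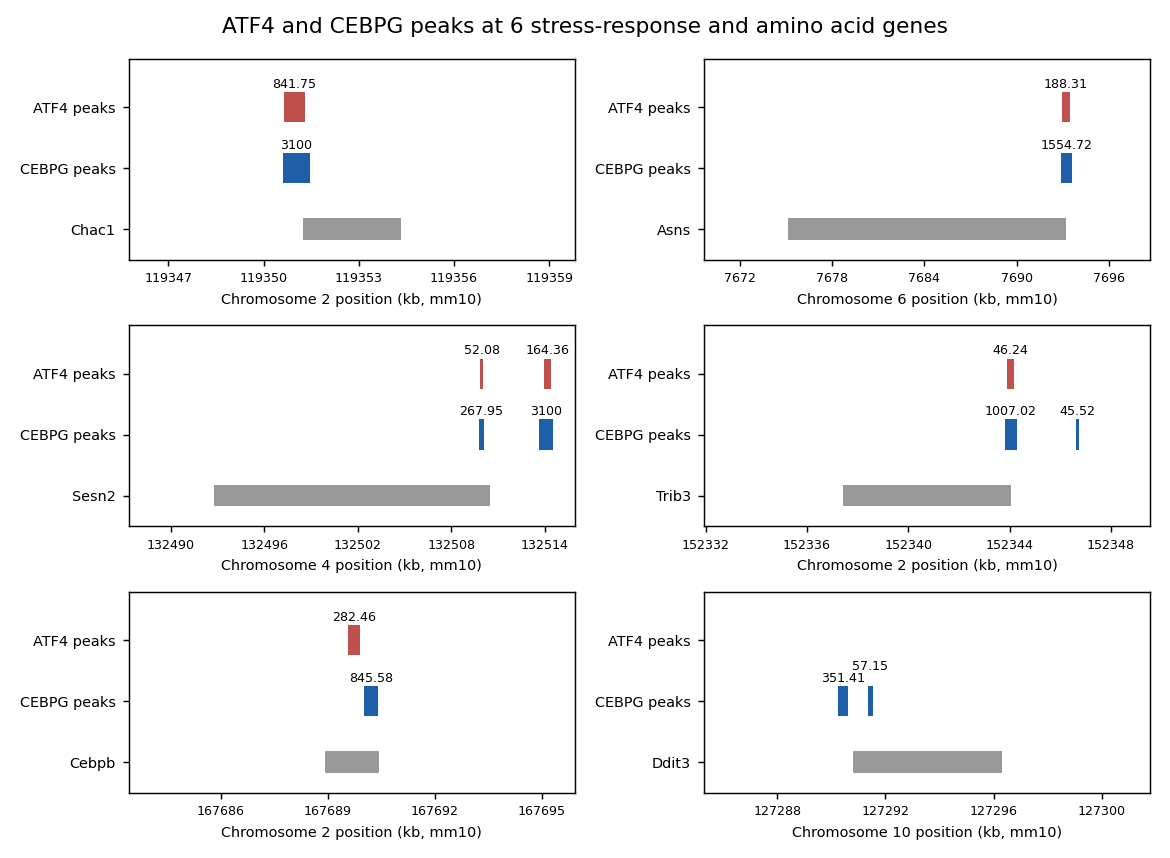
Peak intervals of ATF4 (red) and CEBPG (blue) around 6 genes (grey span), drawn to scale against the mm10 position in kb, with each peak's score above it. Peaks within 5 kb of the gene span are drawn; at Chac1, Asns, Sesn2 and Trib3 both factors overlap, at Cebpb the peaks are adjacent, and at Ddit3 no ATF4 peak was listed.

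Aminoacyl-tRNA synthetases, which charge transfer RNAs, carried a CEBPG peak at 14 of 20 genes (random mean 3.28, adjusted permutation p = 0.00035). ATF4 peaks were at 4 of them (random mean 0.405, adjusted permutation p = 0.0028), all overlapping CEBPG peaks. These were Yars (ATF4 score 127.88), Iars (122.81), Sars (102.68) and Gars (51.78). Amino acid transporters carried a CEBPG peak at 10 of 13 genes (random mean 2.16, adjusted permutation p = 0.00035), including Slc38a7 (1083.45), Slc1a5 (1043.53) and Slc7a1 (539.13). Low scores near an end were at Slc3a2 (60.82), Slc7a5 (59.7), Slc36a4 (43.93) and Slc38a1 (40.27). At scores of 100 or more, 6 of 13 had a CEBPG peak and the list still passed (adjusted permutation p = 0.00035). The single transporter with an ATF4 peak near an end was Slc38a2 (42.46), away from its CEBPG peak (274.94), and the list did not pass for ATF4 (adjusted permutation p = 0.406). Wider windows changed that call. Within 20 kb of an end, 4 of 13 transporters had an ATF4 peak (adjusted permutation p = 0.0143). Slc7a11, the cystine transporter, carried overlapping peaks inside its gene span (ATF4 score 153.06, CEBPG 3100). The ATF4 peak was 55449 bp from the nearest end, outside that window. Slc7a5, named after its values were seen, had overlapping peaks inside its span (230.21 and 3100), with the ATF4 peak 9090 bp from an end. Whether either pair lies at a start inside the span could not be told without transcripts.

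Autophagy genes carried a CEBPG peak at 7 of 14 genes (random mean 2.31, adjusted permutation p = 0.0132), among them Atg16l1 (432.77), Atg10 (394.07) and Becn1 (116.47). This call was lost within 20 kb (9 of 14, adjusted permutation p = 0.0976). Sqstm1, the autophagy receptor p62, was the 1 member with an ATF4 peak (90.93, CEBPG 676.73). Of the extracellular matrix list, 3 of 22 genes had an ATF4 peak (random mean 0.444, adjusted permutation p = 0.0318), namely Col1a2 (50.52), Col5a1 (45.18) and Postn (40.08). None of these peaks reached a score of 100 or lay within 1 kb of an end, and the call was lost under either limit. A CEBPG peak lay within 5 kb of an end at 7 of the 22 genes, among them Fn1 (156.49), and the list did not pass (adjusted permutation p = 0.116). It did pass within 20 kb (17 of 22, adjusted permutation p = 0.00168) and, in an alternative added after seeing the data, over whole gene spans matched on length (15 of 22, 0.00224).

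The remaining 8 lists did not pass in either peak list at this distance. Endoplasmic reticulum chaperones had 5 of 17 genes with a CEBPG peak (adjusted permutation p = 0.209) and 2 with an ATF4 peak (0.118). Those 2, Hspa5, the chaperone BiP (ATF4 87.43, CEBPG 3100), and Sel1l (77.5 and 1339.93), had overlapping peaks, while Xbp1 (253.41) and Dnajb9 (53) had CEBPG peaks alone. This list passed for ATF4 within 20 kb (4 of 17, adjusted permutation p = 0.032) and for CEBPG at scores of 100 or more (3 of 17, 0.0427). Over whole gene spans matched on length, an alternative added after seeing the data, it passed for both (3 of 17 for ATF4, 0.0346, and 8 of 17 for CEBPG, 0.0246). Glutathione and antioxidant genes had 3 of 16 with a CEBPG peak (Hmox1 148.93, Prdx1 58.18 and Mgst1 46.05, adjusted permutation p = 0.627) and 0 with an ATF4 peak. Amino acid sensing genes had 3 of 17 (0.627) and 1, Rheb (46.42 for ATF4, 503.12 for CEBPG), with Nprl3 (44.43) and Rptor (41.58) for CEBPG. Inflammatory secreted factors had 5 of 18 for CEBPG (0.225), including Cxcl2 (114.05), Il6 (77.33), Ccl2 (58.62) and Ccl7 (44.33), and 0 for ATF4. The list passed for CEBPG within 20 kb (12 of 18, adjusted permutation p = 0.0369). It holds neighbouring genes, such as Ccl2 and Ccl7, which were counted through the same peak (44.33), while random genes were drawn singly. No version with neighbours counted once was run for this list. At scores of 100 or more, 1 of 18 had a CEBPG peak (adjusted permutation p = 0.58). Cytosolic ribosomal protein genes had 8 of 24 for CEBPG (0.0719), led by Rps3 (315.51), Rpl7 (120.2), Rpl13 (55.63) and Rpl10a (51.5), and 0 for ATF4. Within 1 kb of an end, 6 of the 24 ribosomal genes had a CEBPG peak and the list passed (adjusted permutation p = 0.00233), as it did over whole gene spans (8 of 24, 0.0114). Neuronal genes had 2 of 16 for CEBPG (Tubb3 60.34, Syt1 45.79, adjusted permutation p = 0.826) and 0 for ATF4. Macrophage and lymphoid genes had 1 of 16 for CEBPG (Ms4a1 41.76, adjusted permutation p = 0.949). Hepatocyte genes had 5 of 16 for CEBPG, against a random mean of 2.62 (Cps1 81.15, Cyp7a1 52.68 and Arg1 49.95 among them, 0.185). Neither of these lists passed for ATF4 (adjusted permutation p = 0.406 each).

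Restricting random lists to genes with a CEBPG peak asked whether ATF4 peaks were concentrated beyond the presence of any CEBPG peak, whatever its score. Of the 4 lists that passed for ATF4, 3 still did, amino acid synthesis, stress-response regulators and aminoacyl-tRNA synthetases, with 8 of 13, 11 of 18 and 4 of 14 CEBPG-marked genes carrying an ATF4 peak (adjusted permutation p = 0.0007, 0.0007 and 0.0205). The extracellular matrix list did not, with 1 of 7 (adjusted permutation p = 0.636). No list passed once random genes were also matched on their top CEBPG score, an alternative added after seeing the data. The means of random lists were then 5.68, 8.61 and 4.74 genes for these 3 lists, against 8, 11 and 4 (adjusted permutation p = 0.664, 0.664 and 1). The class with the highest scores, 2000 or more, held 42 genes in all, and 39 of them had an ATF4 peak.

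**Figure D3:**
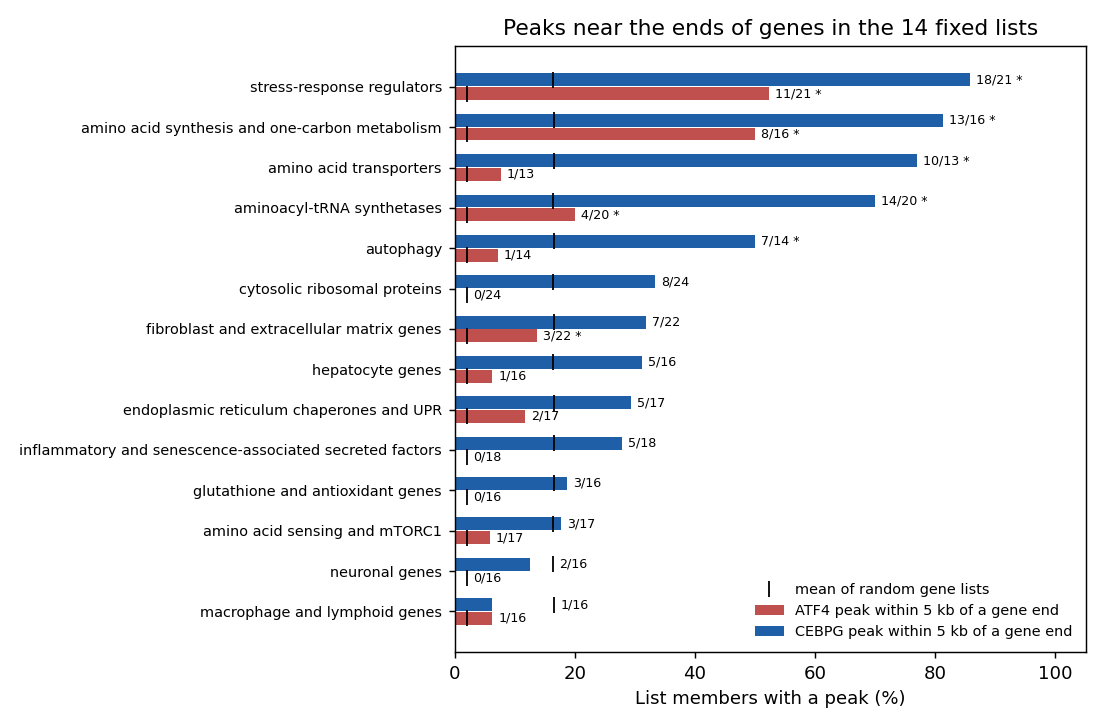
Percent of genes in each of the 14 fixed lists with a CEBPG peak (blue) or an ATF4 peak (red) within 5 kb of either gene end; labels give genes with a peak over genes in the list, vertical ticks the mean of 10000 random lists, and asterisks an adjusted permutation p under 0.05. Stress-response regulators reach 18 of 21 for CEBPG and 11 of 21 for ATF4, while ribosomal protein genes have 0 of 24 for ATF4.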

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

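The alternatives with a score minimum of 50, without peaks over 1 kb wide, with matched scores (of peaks and of genes) and with whole gene spans were chosen after seeing the data. Of 27 alternatives to the overlap, the score differences, the location near gene ends and the number of passing gene lists, 26 were scored as unchanged. For the first 3 results this meant the same direction and side of the threshold. A number of passing lists has no direction, and it was scored from the count alone. The exception was the number of lists passing for ATF4, which fell from 4 to 0 against random genes matched on top CEBPG score. The overlap of ATF4 peaks moved in size. It was 6.74% (178 peaks) when at least 50% of both peaks had to overlap, 15.5% with centres within 250 bp, 357 peaks against as many CEBPG peaks as ATF4 peaks, 15.3% without peaks over 1 kb wide, 34.5% among peaks of score 50 or more and 81.5% among peaks of 100 or more. Random placement 10 to 100 kb from each peak gave 0.649% by chance, an excess of 23.3-fold, the lowest of all settings, and the highest was 598-fold among peaks of 100 or more. For gene location, the difference ranged from 4.49 percentage points with matched scores to 12.7 within 5 kb. The number of passing lists for ATF4 otherwise ranged from 3 to 6, and it was 5 for CEBPG and ranged from 6 to 7. In these alternatives, as few as 3 of the 4 ATF4 calls and 4 of the 5 CEBPG calls were kept by the same lists. Single lists were less stable, and of 140 such results 11 gained a call, 7 lost one and 3 others lost one with a count under the random mean. Gains were the chaperone list in both peak lists, the transporter list for ATF4, and the matrix, ribosomal and inflammatory lists for CEBPG, mostly with wider windows or whole gene spans. Autophagy for CEBPG was lost within 20 kb and over whole gene spans (7 of 14, adjusted permutation p = 0.232). The extracellular matrix list for ATF4 fell to 0 genes both within 1 kb and at a score of 100 or more, where random lists averaged 0.158 and 0.0553 genes, so these are lost calls with no direction to read, and it no longer passed among CEBPG-marked genes (1 of 7) or over whole gene spans (4 of 22). With matched CEBPG scores the synthetases had 4 genes against a random mean of 4.74, which shows no excess. The cause of the matrix changes was not tested, beyond the low scores of those peaks. Motif alternatives were not run, because no genome sequence was used. No paired analysis was possible because there was 1 library per antibody. Depth was unknown, so the lower number of ATF4 peaks cannot be separated from a weaker antibody or a shallower library.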

Other observations

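Of the tests here, those of the overlap of low-scoring ATF4 peaks, of shared peaks near gene ends and of peak width, and the added gene lists, were chosen after seeing the data. The test of shared peaks near gene ends replaced one of ribosomal against stress genes after the result of that one was seen, because the stress list was already known to be enriched. Both factors also marked genes outside the fixed lists. Hspa9, the mitochondrial HSP70, had a CEBPG peak of 3100 centred 292 bp outside its span, overlapping an ATF4 peak of 78.09. Of a list of mitochondrial chaperones and proteases assembled because of it, 8 of 13 genes had a CEBPG peak within 5 kb of an end (random mean 2.13, adjusted permutation p = 0.003), and 7 of the 12 others without Hspa9 (adjusted permutation p = 0.0063). Lonp1 (364.8) and Dnaja3 (193.63) were among them, and the neighbours Hspd1 and Hspe1 were counted through the same peaks (top score 68.53). With that pair counted once and without Hspa9, 6 of 11 genes had a CEBPG peak (adjusted permutation p = 0.0129). Apart from Lonp1 and Dnaja3, these rested on low scores, at the Hspd1 pair, Yme1l1 (67.25), Spg7 (55.63) and Clpx (41.23). Translation initiation factors had a CEBPG peak at 10 of 23 genes (adjusted permutation p = 0.0063), including Eif3c (2141.86), Eif1 (1027.63) and Eif2s2 (295.22). Low scores were also counted here, at Eif4a1 (79.02), Eif5 (75.28), Eif4a2 (50.43), Eif1a (44.1) and Eif2b1 (43.84). The ATF4 peaks of this list, at Eif1 (71.34), Eif3c (54.08) and Eif4a2 (47.92), did not pass (3 of 23, adjusted permutation p = 0.0702).

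Some bZIP genes, picked after their values were seen, carried sites inside the gene. Nfe2l2, encoding the antioxidant regulator NRF2, carried overlapping peaks inside the gene and 10132 bp from an end (ATF4 287.71, CEBPG 2781.52), while 0 of 16 antioxidant genes had an ATF4 peak near an end. Nfil3, a bZIP repressor, had a like pair inside its span (220.73 and 3100). Circadian clock genes had 7 of 18 with a CEBPG peak (adjusted permutation p = 0.0408), which no longer passed without Nfil3 and Arntl (6 of 16, 0.0688). The bZIP genes outside the fixed lists, Nfe2l2 and Nfil3 included, had 10 of 33 with a CEBPG peak and did not pass (adjusted permutation p = 0.0552). Cholesterol synthesis genes had 6 of 17 (0.0552) and cell cycle genes 2 of 18 (0.82) for CEBPG. For ATF4 the circadian, cholesterol and cell cycle lists had 0 genes, the bZIP list 1 (Fosl2, 68.42) and the mitochondrial list 1.

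The first pattern is that most peaks in both lists scored under 50. If these were largely background called at a permissive threshold, they should lie near gene ends about as often as random positions. CEBPG peaks under 50 were within 1 kb of an end 1.10 times as often as random placements (3.32% against 3.03%) and ATF4 peaks under 50 1.12 times (3.45% against 3.08%), against 2.78 and 4.62 times at scores of 100 or more. These values are consistent with a large background share, but background spread evenly over the chromosomes could not produce all of the ATF4 list, where 5.68% of the 1795 peaks under 50 lay on CEBPG peaks against 0.354% by random placement. Background at the same open or repeated places in both libraries stays open, as does weak or distal binding, and neither was tested.

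The second pattern is that high-scoring ATF4 peaks lay on CEBPG peaks. Recovery of open, highly transcribed gene ends by any antibody was examined only at the outer ends of protein-coding gene spans. Of the 110 shared ATF4 peaks of score 100 or more, 16 (14.5%, 9.16 to 22.3%) were centred within 1 kb of such an end. Recovery at those outer ends could not produce most of the 110. Starts inside gene spans or of non-coding genes were not covered, and neither openness nor transcription was measured. For those 16, for such starts and for open sites elsewhere, the explanation stays open. The replaced test (0 of 24 ribosomal and 10 of 21 stress genes with a shared peak, Fisher's exact p = 0.000111) does not decide it, as CEBPG alone marked 8 of the 24 ribosomal genes. Recovery of CEBPG itself by the ATF4 antibody cannot be told apart from joint binding, with CEBPG peaks of 500 or more near amino acid and stress genes overlapping ATF4 peaks in 20 of 35 cases (57.1%) and those elsewhere in 250 of 626 (39.9%, Fisher's exact p = 0.0519), groups that also differ in CEBPG score (medians 1151.91 and 924.33), with which overlap rises. A candidate explanation is binding as heterodimers, which no test here separates from binding side by side.

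The third pattern is that high-scoring ATF4 peaks outside the CEBPG list were wide. At scores of 100 or more, the 25 ATF4-only peaks had a median width of 1266 bp against 394 bp for the 110 shared ones, a difference of 872 bp (permutation p = 1e-05), and 15 against 0 exceeded 1 kb. Several clustered at 9230019H11Rik on chromosome 10 and at Sfi1 on chromosome 11. The permutation test counted such neighbouring peaks separately, so its p-value does not describe independent sites. This width difference restates what was first seen in these peaks, and no test of its cause was run. The other 10 were not over 1 kb wide, among them the peak inside Cebpb (315 bp, score 282.46).

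Peaks were sparse on chromosome X, where their density per base was 0.185 times that of autosomes for CEBPG peaks under 50 (exact 95% interval 0.16 to 0.214) and 0.251 times for those of 100 or more (0.187 to 0.331). For ATF4 peaks the density was 0.0891 times under 50 (0.0444 to 0.16). At 100 or more it was 0.217 times, from only 2 ATF4 peaks on X, with a wide interval (0.026 to 0.799). The CEBPG list held 2 peaks on the mitochondrial genome and the ATF4 list 0.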
